A study of Homo sapiens with 6 samples.

How the data were processed

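Polyadenylated RNA from H1299 cells was sequenced in 6 libraries, 3 from cells given a negative control oligonucleotide and 3 from cells given an antisense inhibitor of tRF3019a. The submitters' processing notes name fastp, HISAT2, STAR, featureCounts and DESeq2 and the human builds hg38 and GRCh38, with no versions, roles or order. Which of the 2 aligners named there made the counts, the gene annotation release and the strand setting are not given in the sources used here. Reads from a gene and an overlapping antisense gene, or from near-identical gene copies, are therefore treated as not separable.

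The main table holds FPKM per gene and library as the authors deposited them, that is fragments scaled to gene length and library size. Per the file headers, it also holds a mean normalized signal per group, which the authors made by dividing counts by DESeq2 size factors. The authors' deposited fold change, as a ratio, and its log2 value compare inhibitor with control. The authors also deposited a p-value and a q-value per gene, from DESeq2 per the series design text. Another of the authors' files holds 106 genes past an unadjusted p of 0.05 and 2-fold, and a further file gives the sum of FPKM per library over 34415 genes. The table of all genes lists 18194 of them, which hold over 99% of the summed FPKM (99.985% in control replicate 1).

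The deposited FPKM and mean signals together fix the number of reads behind each value, and 100% of values came out whole within a tolerance of 0.01 reads. The recovered totals were 30.2, 38.1 and 36 M reads in control replicates 1, 2 and 3 and 36.9, 36.5 and 36.2 M in inhibitor replicates 1, 2 and 3. Because the values as deposited are FPKM, the test laid down for counts was replaced by the one laid down for FPKM, both written before the data were examined. Genes with an FPKM of at least 1 in at least 3 libraries were kept (11656 genes), and log2(FPKM + 1) was compared between the groups with limma 3.58.1 (trended, robust empirical Bayes moderation) in R 4.3.3. All log2 fold changes are inhibitor minus control on this scale, which understates changes of genes with low FPKM. P-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. No covariate was fitted, since every library carries the same batch label.

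Gene lists (35, fixed before the data were examined) were tested with limma's camera with a preset inter-gene correlation of 0.01 where at least 3 members passed the filter (33 lists), with Benjamini-Hochberg adjustment over the lists. Members were also adjusted over the list alone. Genes named in the text follow a rule fixed at the same time. It takes HNRNPK and FBXO47. It then takes the protein-coding genes past the adjusted threshold with at least 5 CPM and no overlap between groups, or, where fewer than 5 pass in a direction, the 8 with the smallest unadjusted p there. It adds up to 4 members of each list by smallest p, and the 3 risen and 3 fallen genes with the smallest p in the authors' deposited table. Other genes named were chosen after their values were seen, whether or not the text repeats this. Genomic positions are from RefSeq on GRCh38.

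Alternatives tried were a pseudocount of 0.1, no filter, a filter of at least 1 CPM in all 6 libraries, limma-voom on the recovered reads, the replicate number as a block, each library left out in turn, the correlation in camera estimated per list, and fry in place of camera. Further ones were added after seeing the data, among them library weights, rescaling of FPKM, removal of a GC and length trend, limma-voom without control replicate 2 and a fit without control replicates 2 and 3. In all, the gene counts were remade under 18 alternatives and the list counts under 21. GC content came from GENCODE 29 transcripts and covered 83.9% of genes. Marker lists for intestinal epithelium, fibroblasts, hepatocytes and neurons were written after 21 genes had been seen to differ between libraries, held none of these, and were set beside the fixed immune and endothelial lists.

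The test was tried on simulated reads with the real means and library sizes, 50 genes at each of 4 fold sizes and 11628 genes in the fit. Every gene was given the same dispersion between replicates, 0.00117, and no clusters of libraries were put in. Recovery in the real libraries may therefore be lower. With 6 regular libraries it recovered 41 of 49 genes at 1.25-fold, 50 of 50 at 1.5-fold, 50 of 50 at 2-fold and 50 of 50 at 4-fold, with 18 false calls. With the deviation of control replicate 2 put into 1 simulated control, it recovered 1 of 49 at 1.25-fold, 33 of 50 at 1.5-fold, 43 of 48 at 2-fold and 49 of 49 at 4-fold, with 1 false call.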

Results

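H1299 is an established human lung cancer line, and tRF3019a is a small RNA derived from a transfer RNA. Cells received 50 nM of an antisense inhibitor of this fragment or of a negative control oligonucleotide, and polyadenylated RNA was sequenced 48 h later. There were 3 libraries per group, with 30.2 to 38.1 M reads assigned to genes per library. The series design text calls them biological replicates, and nothing further says that they were separate cultures, so the p-values measure the spread between these libraries, which may be technical. The level of the fragment itself was not analysed here.

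The first comparison asked which mRNAs differed between inhibitor and control. Differences were small, and no gene among the 11656 tested was separated from the control after adjustment. HNRNPK, the RNA-binding protein whose targets the series design names (chromosome 9, 83968083 to 83980615), was at an FPKM of 374 ± 12.2 (SD, n = 3) in control and 362 ± 5.45 in inhibitor libraries. Its log2 fold change was -0.05 (SE 0.05, 95% interval -0.16 to 0.07), with a limma adjusted p of 0.844. FBXO47, an F-box protein gene on chromosome 17 (38936432 to 38967403), was near the floor of detection, with an FPKM of 0.0565 ± 0.0402 in control and 0.0283 ± 0.00594 in inhibitor libraries, and was not tested.

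Of the protein-coding genes whose libraries did not overlap between groups, HSD17B8, a mitochondrial fatty acid synthesis enzyme on chromosome 6 (33204655 onward), had the smallest unadjusted p. Its FPKM was 10.5 ± 0.345 (SD, n = 3) in control and 8.48 ± 0.189 in inhibitor libraries, a log2 fold change of -0.28 (SE 0.06, limma adjusted p 0.844). The others on the lower side were RMI2 of the BLM complex (log2 fold change -0.24, SE 0.06), SERF2 (-0.21, SE 0.05), the pre-rRNA processing factor RRP9 (-0.27, SE 0.07), the augmin subunit HAUS8 (-0.21, SE 0.06), the LIM-domain protein AJUBA (-0.24, SE 0.07), the ubiquitin ligase RNF114 (-0.25, SE 0.07) and GAGE2A. GAGE2A, a cancer-testis antigen gene on the X chromosome, had an FPKM of 57.6 ± 9.12 in control and 28.4 ± 10.6 in inhibitor libraries, a log2 fold change of -1.06 (SE 0.28). It belongs to a family of near-identical copies, so its reads cannot be assigned to it with certainty. On the higher side stood C15orf65 (log2 fold change 0.28, SE 0.08), the exonuclease ERI2 (0.25, SE 0.08), the zinc finger gene ZNF586 (0.23, SE 0.07), ARID5B (0.22, SE 0.07), the small Maf protein MAFK (0.21, SE 0.07), SPATA33 (0.21, SE 0.07), FAM81A (0.20, SE 0.06) and ZCCHC10 (0.18, SE 0.05). These 16 genes are named as the smallest unadjusted p in each direction, and all 16 missed the adjusted threshold.

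**Figure D1:**
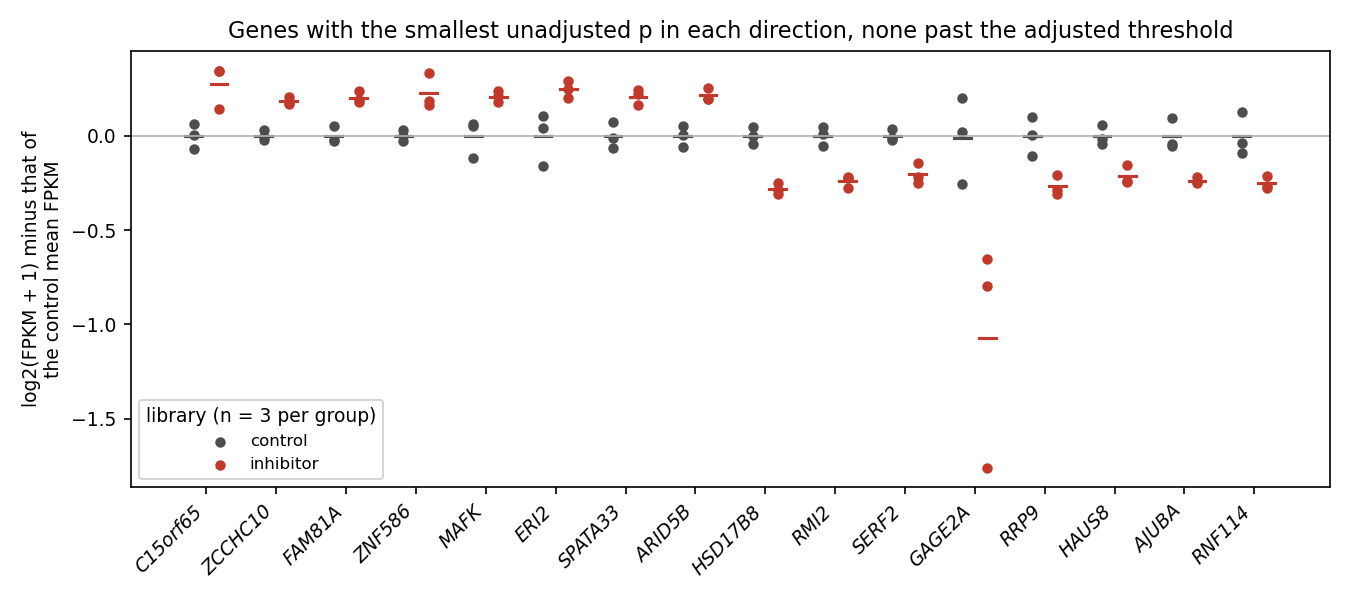
Expression of the 16 genes in each library, as log2(FPKM + 1) minus the value of the control mean FPKM, with a bar at each group mean (n = 3 per group, grey control, red inhibitor). The libraries of the groups do not overlap for any of the 16, by selection, and GAGE2A, at a log2 fold change of -1.06, is the one beyond 2-fold.

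In all, limma placed 0 genes past an adjusted p of 0.05 (lowest 0.844), and limma-voom on the recovered reads also placed 0 (lowest 0.811). At an unadjusted p under 0.05 there were 222 genes (82 higher, 140 lower) with limma and 211 with limma-voom, where chance gives 582.8 in a calibrated test. In the simulation with the deviation of control replicate 2, 1.6% of unchanged genes had an unadjusted limma p under 0.05. The share here was 1.905%, so the 222 cannot be read as fewer than chance. The 3 inhibitor libraries lay wholly above the controls for 386 genes and wholly below for 663, together 9% of the genes tested, where chance gives 10%. The 222 depended on single libraries: 740 without control replicate 1, 306 without control replicate 3, and 91, 96 and 126 without inhibitor replicates 1, 2 and 3. Nor was the balance of directions stable, at 151 higher and 152 lower with a GC and length trend removed and 412 and 270 without control replicates 2 and 3, both fits added after seeing the data. At 2-fold and unadjusted p under 0.05 the count was 1, GAGE2A, which met this in 14 of 18 alternatives. It did not with control replicate 2 left out (log2 fold change -1.18, p above 0.05), control replicate 3 (-0.95), inhibitor replicate 3 (-0.71) or control replicates 2 and 3 together (-1.09, p above 0.05), and in the last 3 of these fits another gene kept the count at 1. Control replicate 2 stood apart from the other libraries: without it, 535 genes had an unadjusted p under 0.05 and 0 passed the adjusted threshold (lowest 0.0712).

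The library that stood apart was seen first in its mitochondrial reads. These made up 2.11% of reads in control replicate 2, against 5.8% and 6.11% in control replicates 1 and 3 and 5.81%, 5.66% and 6.32% in inhibitor replicates 1, 2 and 3. The nuclear long noncoding RNAs MALAT1 and NEAT1, named after their values were seen, were at 0.367 and 0.258 of their mean in the other controls in that library. The first principal component, with 71.8% of the variance, separated it from the other 5 libraries. On the second component, with 8.67%, control replicate 3 lay beside inhibitor replicate 3.

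**Figure D2:**
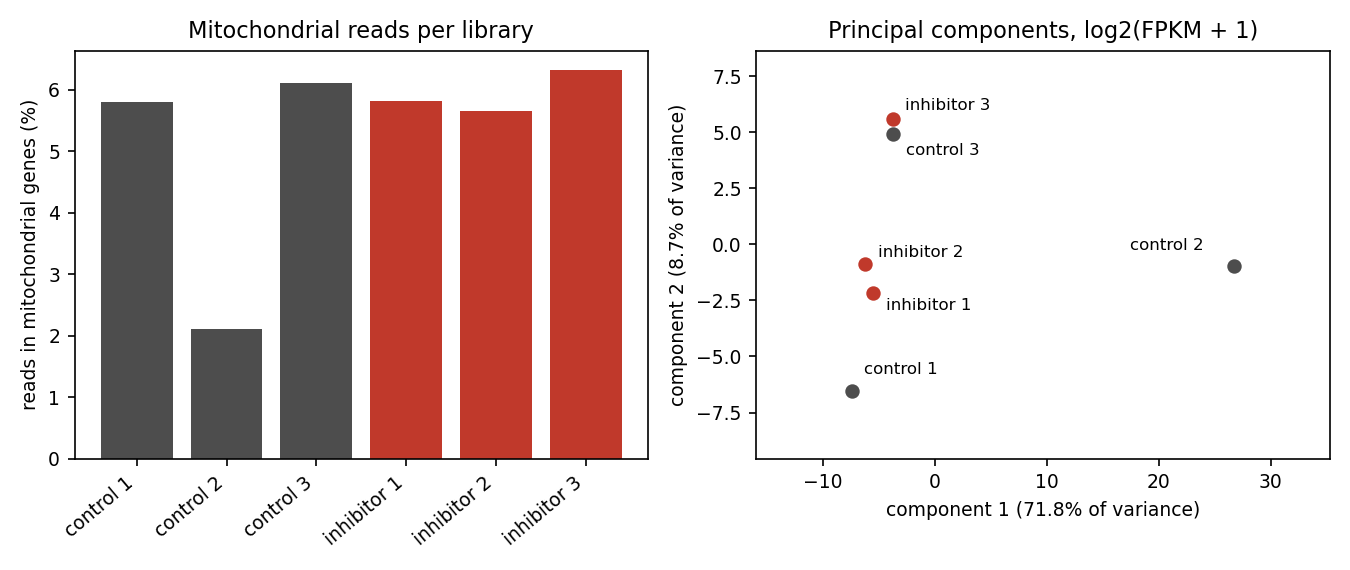
Left, percentage of reads in mitochondrial genes per library; right, the first 2 principal components of log2(FPKM + 1) over the 11656 tested genes, each point 1 library (grey control, red inhibitor). Control replicate 2, with 2.11% mitochondrial reads, lies apart on the first component.

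The second comparison took the gene lists. The 13 mitochondrially encoded mRNAs were all higher in inhibitor libraries (median log2 fold change 0.54) and the list rose against other genes with limma's camera (adjusted p 0.000123). The adjusted p = 0.82 with an estimated correlation. ND4L, a complex I subunit, was at an FPKM of 3638 ± 2051 (SD, n = 3) in control and 4962 ± 228 in inhibitor libraries, and COX1, a cytochrome c oxidase subunit, at 6989 ± 3565 and 9270 ± 462. In the single libraries ND4L was at 4828, 1270 and 4816 in control replicates 1, 2 and 3, and without control replicate 2 the median of the list was 0.00 with an adjusted p of 0.823.

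Of the lists of nuclear genes, 3 passed camera on the lower side. In the nuclear-encoded respiratory chain 28 of 29 members were lower (median log2 fold change -0.07, camera adjusted p 0.00505), for example ATP5MC1 of ATP synthase, at an FPKM of 144 ± 11.3 and 125 ± 9.69, and NDUFA1 of complex I, at 230 ± 24.1 and 207 ± 6.02. Of 24 G1/S and DNA replication genes 20 were lower (median -0.08, adjusted p 0.0113), among them the replicative helicase subunits MCM2, at 41.1 ± 4.83 and 36.2 ± 0.697, and MCM6, at 55.2 ± 3.24 and 50.6 ± 1.24. Of 32 cytosolic ribosomal proteins 29 were lower (median -0.07, adjusted p 0.0347), with RPLP1 at 663 ± 69.3 and 591 ± 31.9 and RPS12 at 1317 ± 83.4 and 1233 ± 27.8. For each of these 3 lists the adjusted p = 0.82 with an estimated correlation, and without control replicate 2 it was 0.637, 0.559 and 0.669 in this order.

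Mesenchymal and matrix genes rose as a list (16 of 24 higher, median log2 fold change 0.07, camera adjusted p 0.000619), with an adjusted p = 0.82 with an estimated correlation and 0.0127 without control replicate 2. The collagenase MMP1 was at an FPKM of 4.30 ± 2.03 in control and 8.34 ± 2.03 in inhibitor libraries, collagen COL1A1 at 1.30 ± 1.07 and 2.59 ± 0.299, fibronectin FN1 at 7.32 ± 1.64 and 9.42 ± 0.527, and tenascin TNC at 3.06 ± 0.298 and 3.64 ± 0.303. COL1A1 did not follow the groups: it had 534, 150 and 134 normalized reads in control replicates 1, 2 and 3 and 605, 548 and 484 in inhibitor replicates 1, 2 and 3. FN1, at an FPKM of 9.21, 6.39 and 6.36 in control and 9.97, 9.37 and 8.92 in inhibitor libraries, and MMP1, at 6.58, 3.63 and 2.68 and 8.86, 10.1 and 6.10, were likewise highest among the controls in replicate 1. Leaving out COL1A1 alone (median 0.07, adjusted p 0.00259) therefore does not free the list of this pattern, and with control replicates 2 and 3 both left out 0 of 33 lists passed. Fibroblast markers, of which 3 were tested, had a median of 0.73 and a camera adjusted p of 0.0807. It was 0.0496 without control replicate 2, 0.0429 with limma-voom and 0.0422 with the replicate block, but 0.82 with an estimated correlation. Their member COL1A2 was at an FPKM of 1.03 ± 1.15 and 2.04 ± 0.152. Of the epithelial genes, 5 of 7 were higher (adjusted p 0.125), with keratin KRT19 at 0.658 ± 0.938 and 1.82 ± 0.419.

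**Figure D3:**
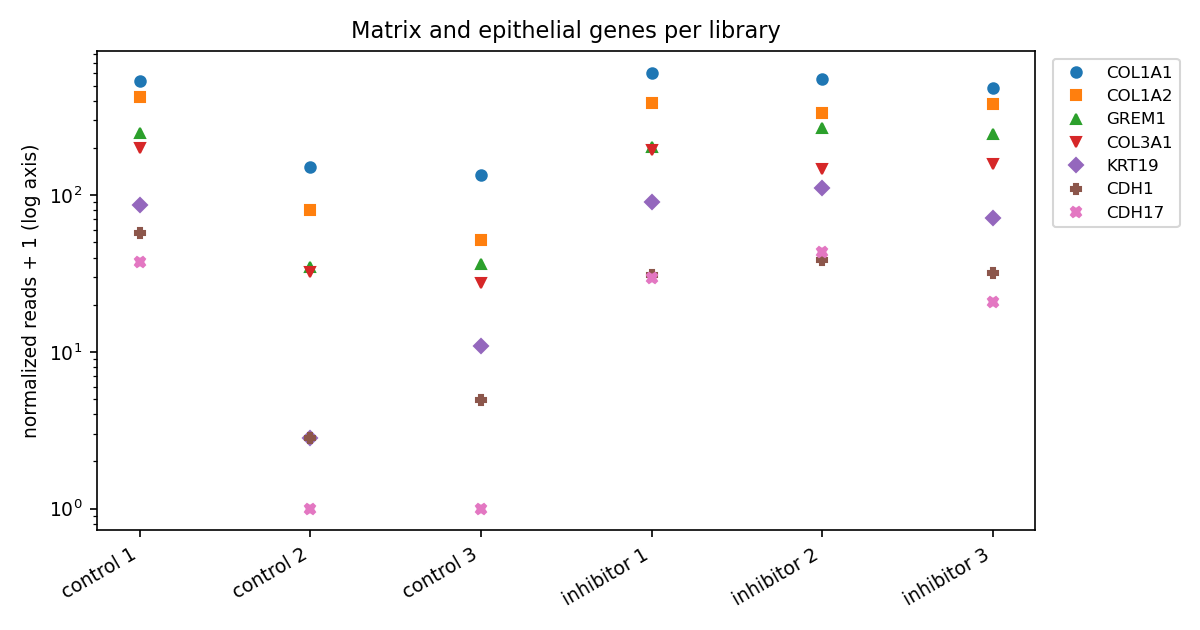
Normalized reads plus 1 (log axis) of 7 matrix and epithelial genes in each of the 6 libraries, 1 marker shape per gene. In control replicate 1 COL1A1 has 534 normalized reads, beside 484 to 605 in the inhibitor libraries and 150 and 134 in control replicates 2 and 3.

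Lists nearer to the fragment's reported partners did not pass. Of 28 members of the hnRNP family, 12 were higher and 16 lower (median log2 fold change -0.03, camera adjusted p 0.887), with HNRNPUL2 at an FPKM of 9.84 ± 0.648 and 8.89 ± 0.191. Of 9 genes linked to hnRNP K, 5 were higher (median 0.03, adjusted p 0.643). In the small-RNA pathway 11 of 19 were higher (adjusted p 0.444), with the tRNA methyltransferases NSUN2 at 28.9 ± 1.10 and 26.6 ± 0.817 and TRMT10A at 3.00 ± 0.444 and 3.52 ± 0.0644. Interferon-stimulated genes, which respond to foreign nucleic acid, were higher in 17 of 25 (adjusted p 0.0978), with IFI27 at 2.17 ± 0.136 and 2.86 ± 0.667 and OASL at 19.6 ± 3.39 and 16.9 ± 0.701. No member of any of the 35 lists passed, either over all genes or adjusted over the list alone.

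**Figure D4:**
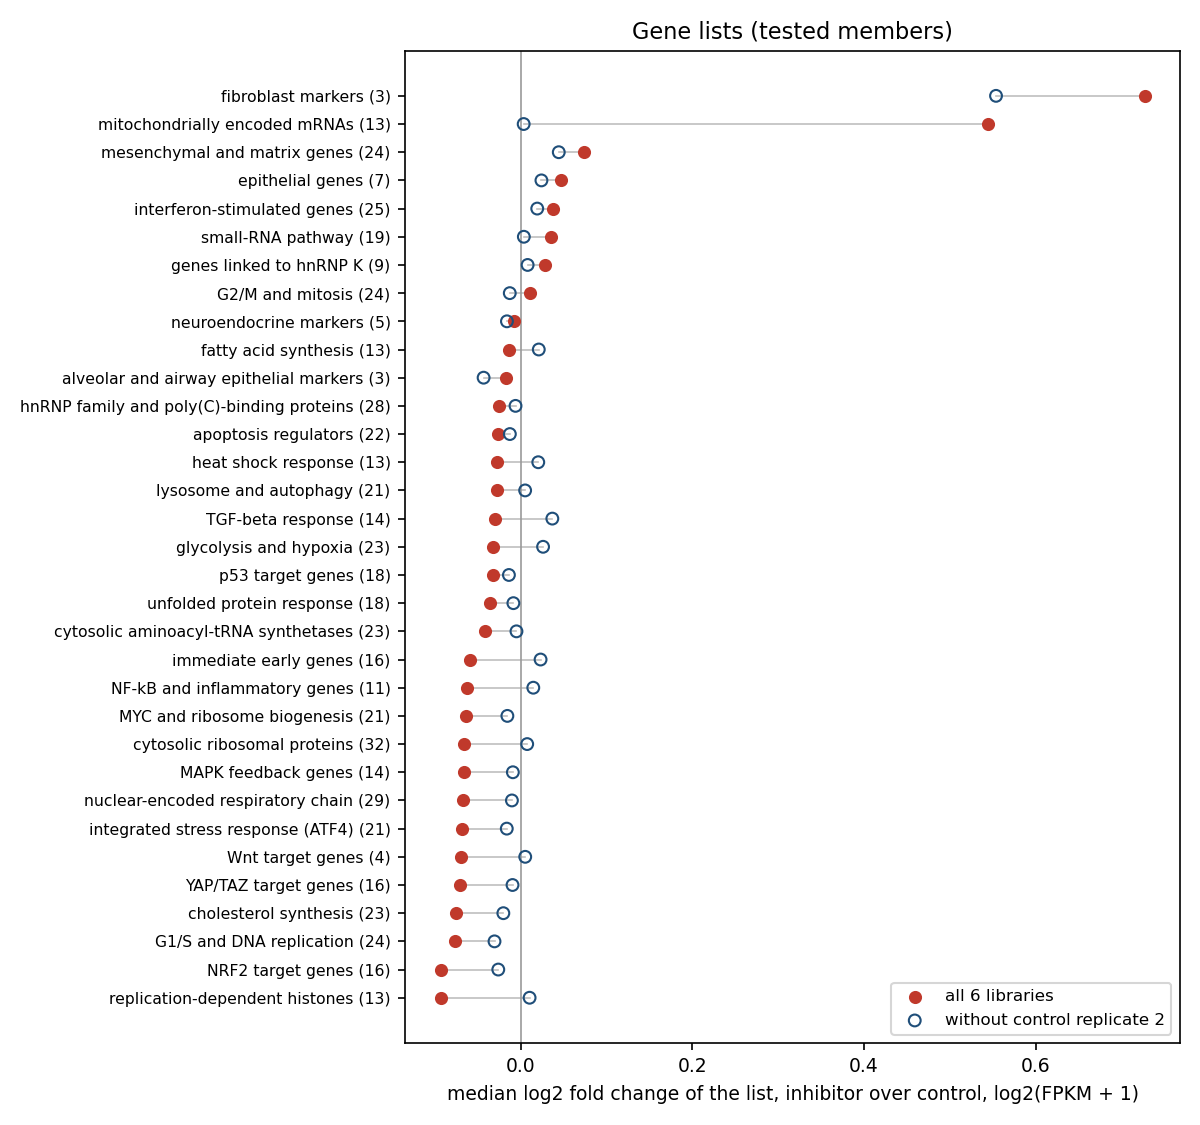
Median log2 fold change (inhibitor over control, log2(FPKM + 1)) of the 33 tested lists, with the number of tested members in brackets, over all 6 libraries (filled) and without control replicate 2 (open). The mitochondrially encoded mRNAs move from 0.54 to 0.00 when control replicate 2 is left out.

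The third comparison set these values beside the authors' deposited table. Of 18194 genes in the authors' deposited table, 318 had an unadjusted p under 0.05 and 0 had a q under 0.05. The 3 higher genes with the smallest p in the authors' deposited table, all with a q above 0.05, were periostin POSTN with a log2 fold change of 2.15, the hyaluronan synthase HAS2 with 1.88 and the muscle caveolae gene CAVIN4 with 1.11. On the lower side the authors' deposited table had GAGE2A at -1.01, TBC1D3H, also of a multi-copy family, at -1.89, and the ribosome biogenesis gene PWP2 at -0.42. POSTN rested on an FPKM of 0.0569 ± 0.0321 (SD, n = 3) in control and 0.246 ± 0.0444 in inhibitor libraries, and HAS2 on 0.0610 ± 0.0283 and 0.220 ± 0.0677. Of the 106 genes past 2-fold and unadjusted p in the authors' deposited table (71 higher, 35 lower), 95 had an FPKM under 1 in every library and 6 entered the limma test. Across the 11656 shared genes the log2 fold changes correlated with the authors' deposited table at Pearson r = 0.962 and Spearman rho = 0.993, across genes, which are not independent replicates. Of the 222 genes at unadjusted p under 0.05 with limma, 109 were so in the authors' deposited table too, all 109 with the same sign.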

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

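The alternatives laid down for edgeR and DESeq2 were not run, since the values as deposited are FPKM, although the recovered reads, used for limma-voom, would have allowed them. Library weights, rescaling, trend removal, the cluster term, limma-voom without control replicate 2 and the fit without control replicates 2 and 3 were chosen after seeing the data. The count of genes past the adjusted threshold was 0 in 16 of 18 alternatives, each replicate left out included. It was 1 with library weights (THORLNC) and 2 with control replicates 2 and 3 left out (LOC105372632 and SLC25A6), 3 genes named after their values were seen; the lone control is assumed to vary like the inhibitor libraries. The replicate block gave 0 genes, 1 gene at 2-fold and 6 lists, and the deviations of same-numbered libraries from their group means had correlations of 0.0792, -0.134 and -0.0462, which control replicate 2 dominates, so whether the numbers pair the libraries stays open. The 2-fold count of 1 became 7 with a pseudocount of 0.1, 9 with limma-voom, 6 with limma-voom without control replicate 2, 2 with library weights, and 0 (without control replicate 2) to 5 (without control replicate 1) with 1 library left out. Of the lists, 5 passed in the fit as reported, 8 with no filter, 2 with library weights, 3 with limma-voom without control replicate 2, 2 with library clusters as a term, and 0 with control replicates 2 and 3 left out, an estimated correlation or fry. With 1 library left out the count ran from 2 (without inhibitor replicate 2) to 8 (without control replicate 1). The direction camera gives turned in 8 of 100 list values, not always with the median. Mitochondrially encoded mRNAs had a median of 0.0034 without control replicate 2 (0.0032 with limma-voom), against 0.84 without control replicate 3. Ribosomal proteins had 0.0075 without control replicate 2 (0.0073 with limma-voom, 0.0174 with the cluster term), -0.11 without control replicate 1 and 0.0222 with control replicates 2 and 3 left out. In that last fit G1/S genes had -0.0058, respiratory chain genes -0.0022 and COL1A2 -0.14. For the other alternatives the cause was not tested. Of 51 tested genes named in any part, 4 turned, in 7 of 914 values. FBN1 had -0.044 and MALAT1 -0.036 with control replicates 2 and 3 left out, and NEAT1 had 0.91 without control replicate 1, -0.086 without control replicate 2 (-0.0864 with limma-voom, -0.11 with the cluster term) and -0.17 with control replicates 2 and 3 left out. In that fit LOC105372632 had -0.75 (-0.63 as reported) and SLC25A6 -3.88 (-1.30 as reported, SE 0.96, FPKM 13.7 ± 20.8 in control and 1.65 ± 0.27 in inhibitor libraries, so the call rests on the 1 control kept), and THORLNC had 0.61 with library weights (0.50 as reported). Genes under 1 FPKM in most libraries were left out of the test, and how far depth limits them was not tested. Control replicate 2 limited small changes in the simulation, which gave every gene the same dispersion. Recovery at the smallest fold was 41 of 49 genes without its deviation and 1 of 49 with it.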

Other observations

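The list tests and the limma fit without control replicate 2 were planned; the tests of families, library patterns and splits were chosen after the patterns were seen, with the bounds of the GC and length trend for control replicate 2 and of the first marker test written before their values. None of the lists not described above passed over all 6 libraries. NRF2 target genes were lower in 13 of 16 (median log2 fold change -0.09, camera adjusted p 0.0807), cholesterol synthesis genes in 19 of 23 (-0.08, 0.0807), MAPK feedback genes in 11 of 14 (-0.07, 0.0807) and replication-dependent histones in 10 of 13 (-0.09, 0.342). These falls leaned on control replicate 2. With it left out, the medians were -0.026, -0.020, -0.0092 and 0.010 in this order (camera adjusted p 0.559, 0.823, 0.972 and 0.972). Unfolded protein response genes were lower in 13 of 18 (camera adjusted p 0.295), with the ER-stress protein HERPUD1 at an FPKM of 12.1 ± 0.156 (SD, n = 3) in control and 10.7 ± 0.149 in inhibitor libraries and CRELD2 at 5.43 ± 0.519 and 4.61 ± 0.241. YAP/TAZ target genes were lower in 12 of 16 (adjusted p 0.091), with the receptor kinase AXL at 172 ± 9.87 and 156 ± 0.292 and the matricellular gene CCN2 at 5.58 ± 0.131 and 4.98 ± 0.139. In the fit without control replicate 2, the unfolded protein response and YAP/TAZ lists had medians of -0.0086 and -0.0096 (camera adjusted p 0.604 and 0.468). In G2/M and mitosis 13 of 24 were higher (adjusted p 0.643), with DLGAP5 at 43.1 ± 1.71 and 47.6 ± 0.132 and the kinase AURKB at 35.6 ± 2.08 and 32.3 ± 0.763. Glycolysis and hypoxia genes had an adjusted p of 0.887 over all 6 libraries and of 0.0496, higher, without control replicate 2, with a median log2 fold change of -0.03 and 0.03 in turn. Over all 6 libraries they had an adjusted p = 0.962 with an estimated correlation, which was not run without control replicate 2. Immune markers had 1 tested member and endothelial markers 2, too few for the list test.

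The GAGE genes were then summed, since their copies share reads. Over 9 listed GAGE genes the sum was 61.9 ± 3.71 CPM (SD, n = 3) in control and 42.9 ± 6.17 in inhibitor libraries, lower in 3 of 3 inhibitor libraries. Its two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows (0.2 adjusted over 2 families). That p is no independent test, since GAGE2A, picked for libraries that did not overlap between groups, held 32.1 CPM of the control sum. Of the 9 members 6 were lower and 3 higher, and the sum without GAGE2A was not tested. GAGE2A was at 58.4, 48.0 and 66.2 FPKM in the control and 36.2, 32.7 and 16.3 in the inhibitor libraries, while GAGE13 was at 3.54, 5.62 and 4.06 and 6.13, 5.67 and 7.15. The 4 listed TBC1D3 genes, which include TBC1D3H, likewise picked for its fall, summed to 3.47 ± 1.28 and 2.20 ± 0.771 CPM (exact permutation p 0.3, 0.3 adjusted).

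Control replicate 2 stood apart from the other 5 libraries. Against the other controls, 302 of 11643 nuclear genes were over 2-fold away, 286 of them lower, where control replicates 1 and 3 had 44 such genes between them. Loss of mitochondrial reads alone is argued against, since nuclear genes differed 2.67 times as much as between the other controls. Its distance from the inhibitor libraries was 2.88 times the distance among them. This cannot tell whether it is an inhibitor library under a control label, since it lay about as far from the controls. Control replicate 2 had median absolute log2 differences of 0.1855 and 0.164 from control replicates 1 and 3, and of 0.1741, 0.1815 and 0.1672 from inhibitor replicates 1, 2 and 3. GC content and gene length explained 28.8% of the variance of its nuclear log2 ratios (Spearman rho 0.609 with GC and -0.284 with length, across genes), between the bounds of 10% and 50% set for it, so a GC or length bias remains a candidate explanation for a part. A difference between cultures stays open, untested.

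Intestinal and matrix transcripts were high in control replicate 1 and the inhibitor libraries and low in control replicates 2 and 3: 21 genes, among them CDH17, VIL1, HNF4A, FABP1, KRT19, COL1A1, COL1A2 and GREM1, named after their values were seen, summed to 60.1, 10.3 and 9.4 CPM in the control and 59.8, 57.8 and 54 CPM in the inhibitor libraries, while the same rule gave at most 1 gene for the other 14 pairs of libraries. The median ratio of the inhibitor libraries to control replicate 1 over these genes, 1.00, is no test of the inhibitor, as they were chosen with control replicate 1 high. Without that choice, 23 genes were over 3 times as high in the inhibitor libraries as in control replicates 2 and 3, 21 of them the same. Their median ratio to control replicate 1 was 1.02 (POSTN at 2.33 and PLEKHG6 at 2.25 were the exceptions). This argues against an inhibitor effect only if control replicate 1 is a control as labelled. That was not tested, and this library clustered with inhibitor replicates 1 and 2. RNA from other cells, or reads from another sample, was tested 2 times. By the bounds set for it the first test argued against this, with a ratio of summed marker CPM, 4 libraries over 2, of 1.14 for intestinal and 1.00 for fibroblast markers where 2 was needed and under 1.5 counted against; it was set aside only after that result, because members above 10 CPM, such as ANPEP and FBN1 (1 of 8 and 7 of 13), held 96.4% and 97.6% of the sums and would hide a small share. The second took markers under 1 CPM, with a bound of 1.5 chosen after the marker values were seen. Its ratios of the lowest of the 4 to the highest of the 2 were 1.67 for 7 intestinal and 1.84 for 3 fibroblast markers. They were 0.893 for hepatocyte, 0.302 for neuron, 0.168 for immune and 0.807 for endothelial markers. LYZ ran opposite to the pattern, at 0, 0.736 and 0.862 CPM in the control and 0, 0 and 0.0553 in the inhibitor libraries. It lowered the immune ratio, while CD74 went with the pattern (0.232, 0 and 0, then 0.298, 0.137 and 0.249). NEFL, at 1.18 CPM in control replicate 2, lowered the neuron ratio. Singly, 4 of the 7 and 2 of the 3 markers followed (LGALS4, CDX2, MYO1A and MFAP5 did not). MXRA5 followed only by 0.135 CPM in inhibitor replicate 1 against 0.131 in control replicate 2. Without FAP the fibroblast ratio was 0.638, so the source stays open.

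The other 5 libraries fell into 2 clusters that cross the groups: control replicate 1 with inhibitor replicates 1 and 2 (chi-square per gene 2.85 to 3.25 between them), and control replicate 3 with inhibitor replicate 3 (3.44), against 4.57 to 5.26 across. A difference in sequencing depth is argued against, since the smaller cluster had fewer reads in 4 of 6 cross-cluster pairs. GC content and gene length, tested after long genes had been noticed among the differences, explained 10.8% of the variance between the clusters, just above the bound of 10% under which it would have been argued against, so a length or GC bias may be a part of it. The smaller cluster holds replicate 3 of both groups, while the larger mixes replicates 1 and 2, so whether the numbers pair the libraries stays open here too. No biological explanation was tested.

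Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. All 10 splits gave 0 genes past the adjusted threshold. The real split gave 222 genes at unadjusted p under 0.05 and the highest other 683, for control replicate 1 with inhibitor replicates 1 and 2 against the rest, with 3 splits as large, the real one included. That highest split sets the larger cluster against the rest, so it restates the clusters and adds no evidence for them. The 2-fold count was 1 in the real split and 3 in the highest other, with 4 splits as large, and the lists were 5 and 6, with 3 splits as large, the real one included in each.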
